A study of Homo sapiens with 18 samples.

How the data were processed

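RNA was measured in MCF-7 cells in 6 groups of 3 libraries, formed by population (TFF1high or TFF1low), RNA fraction (chromatin-bound nascent or polyA) and experiment. There were 12 nascent libraries from experiments 1 and 2 and 6 polyA libraries from experiment 1, and groups and replicate letters were taken from the sample titles. By the labels, nuclei were purified on a sucrose cushion, chromatin was extracted with a urea buffer, and directional libraries were made with or without polyA selection. The submitters call the polyA libraries total RNA.

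Per the submitters' processing notes, reads were aligned with STAR to hg38 and each deposited table holds a count per gene from featureCounts, with no normalization. The versions of these tools, the strand setting, and whether exons or whole genes were counted are not given in the sources used here. Overlapping genes on opposite strands (such as MT-ND6 and SOCS3-DT) and near-identical copies (histone genes, and ribosomal protein genes with their pseudogenes) therefore have uncertain counts. The tables had no header, held whole numbers only, and listed 61228 gene names, all of them names in GENCODE release 44. In that release 343 names are shared by 1815 gene loci, so these were measured as merged entries.

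Library totals, in units of 1e+06 counts, ran from 2.61 to 12.4 in nascent experiment 1 TFF1high, 3.52 to 23.0 in TFF1low, 2.77 to 2.86 in nascent experiment 2 TFF1high and 1.86 to 9.86 in TFF1low. For polyA they ran from 13.9 to 47.5 in TFF1high and 15.7 to 50.5 in TFF1low. At these depths 3 counts equal 1.61 CPM in the smallest library and 0.0594 CPM in the largest, and counts of PCR copies are not independent molecules.

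Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Libraries were scaled by TMM, genes were filtered with filterByExpr by group, and group means were compared with the edgeR quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment at 0.05 over all genes tested. The 12 nascent libraries were fitted together, the 6 polyA libraries alone, and the 12 libraries of experiment 1 together for contrasts between fractions. The contrasts were TFF1high against TFF1low in each experiment and fraction, the difference of that effect between experiments and between fractions, and nascent against polyA level. Log2 fold changes are from the edgeR fit, their standard errors follow from its F statistic, and CPM values given with SD are TMM-adjusted unless called plain. Shares of counts were compared with an exact two-sided permutation test.

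Gene lists, comparisons, tests and the rule for named genes were written before the data were examined. The 27 lists held 11 to 55 genes: estrogen-induced, estrogen-repressed, TFF locus, receptor and cofactors, Polycomb repressive complexes 1 and 2, polycomb targets, G1/S, G2/M, histones, p53, immediate early, heat shock, unfolded protein response, hypoxia, cholesterol synthesis, interferon, luminal, basal and mesenchymal, stem-like, immune, secretory, ribosomal protein, mitochondrial, oxidative phosphorylation, chromatin-retained, and endocrine resistance. TFF1 is in none. Each was tested with limma camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, again with the correlation estimated, and with fry, with adjustment over lists. Members were also counted with p adjusted over the list alone. Chromosomes were tested as sets in the same way. With the correlation estimated, camera also takes its degrees of freedom from the fit (8 in nascent and cross-fraction fits, 4 in polyA). Adjusted p can then rise even where genes do not correlate, so a lost call is not in itself a sign of correlation.

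Named genes were TFF1, ESR1, PGR, GREB1, EZH2 and MKI67, then up to 10 genes per direction with the largest change among those that passed, had a mean CPM of at least 2, kept all libraries of one group above all of the other, and were neither pseudogenes nor clone names. Up to 4 members of each list with the smallest p were added. Where fewer than 5 genes passed, the 5 with the smallest p were taken.

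Alternatives were RLE scaling, library size only, no filter on low counts, another threshold, a minimum fold of 1.2, DESeq2, limma-voom, the replicate letter as a block, other sets of libraries in the fit, TFF1 and mitochondrial genes left out, and each library left out in turn. Thinning of the counts, and leaving out mitochondrial and ribosomal protein genes, were added later. The pipeline was tested on simulated counts with known changes. Each gene was drawn independently from a negative binomial distribution, with its mean share over the fitted libraries and the trended dispersion. Such counts hold no correlation between genes and no level difference between fractions, so recovery in the real libraries may differ. Recovery of 2-fold changes was 64.2% in nascent experiment 1, 49.3% in nascent experiment 2 and 83.6% in polyA, with 5, 6 and 8 false calls, and a list shifted 1.5-fold was called each time. No library was left out of the analysis. Each pair of libraries within a group was checked for duplication, and every pair differed by more than sampling noise (chi-square per degree of freedom from 2.79 to 14.2).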

Results

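MCF-7 cells, an established estrogen receptor positive breast cancer line, were grown without hormone for 72 h and then given 1 nM estradiol. RNA was profiled in populations that the labels call TFF1high and TFF1low, after a small secreted peptide whose gene is a classical estrogen receptor target. The series asks how uneven chromatin states, H3K27me3 in particular, go with uneven responses to estrogen among such cells. Chromatin-bound nascent RNA was sequenced in experiments 1 and 2 and polyA RNA in experiment 1, with 3 libraries per group and 18 libraries in all. The names of the deposited tables call the experiment 1 populations a top fraction and the rest, and the experiment 2 populations not negative and negative. The means of separation are not given in the sources used here. No library without estradiol is among these samples. The estradiol exposure is 48 h in the sample labels and 24 h in the treatment protocol. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries.

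TFF1 itself differed between the populations in the direction of their names. In nascent RNA of experiment 1 it was 4.62-fold higher in TFF1high libraries (log2 fold change 2.21 ± 0.25 SE, 280 ± 89.4 against 58.8 ± 26.1 CPM, counts scaled to the library total, mean and SD, n = 3 per group). The difference was 7.78-fold in nascent RNA of experiment 2 (2.96 ± 0.29) and 6.87-fold in polyA RNA (2.78 ± 0.05). Because the populations carry the gene's name, this shows that the libraries follow their labels and is no independent result.

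**Figure D1:**
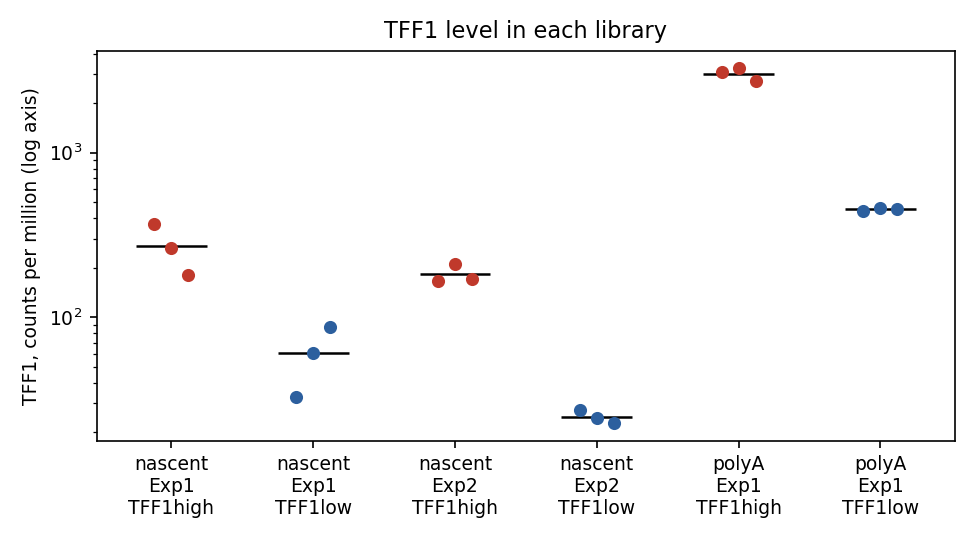
TFF1 in each of the 18 libraries, in CPM on a logarithmic axis, with TFF1high libraries in red, TFF1low libraries in blue and a black bar at each group's mean. The means, on plain library totals, were 271 and 60.3 in nascent RNA of experiment 1, 182 and 24.9 in nascent RNA of experiment 2, and 3019 and 454 in polyA RNA.

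In nascent RNA of experiment 1, TFF1high cells had more nascent RNA from estrogen-induced genes and from genes of the G1/S transition, and less from basal and mesenchymal markers. GREB1, an estrogen receptor target and coregulator, rose 1.91-fold (log2 0.93 ± 0.10 SE, n = 3 per group), while ABCA1, the cholesterol efflux transporter, was 8.45-fold lower (−3.08 ± 0.26; 4.09 ± 0.596 against 35.5 ± 6.03 CPM). Of 54 estrogen-induced genes measured, 24 rose, 2 fell and 28 did not pass (29 and 4 passed when adjusted over the list alone; median 0.45). Examples were the receptor tyrosine kinase gene RET (2.30-fold), the secreted glycoprotein gene STC2 (1.06 ± 0.10) and the small heat shock protein gene HSPB8 (1.79 ± 0.20). Of 37 G1/S genes 14 rose and none fell (24 rose when adjusted over the list alone; median 0.48, or 1.40-fold), among them the replicative helicase genes MCM5 (0.82 ± 0.12) and MCM3 (0.63 ± 0.11) and the replication licensing regulator DTL (1.03 ± 0.18). Of 10 measured basal and mesenchymal markers 5 fell, 1 rose and 4 did not pass (7 and 1 when adjusted over the list alone; median −0.82). TP63, a basal cell transcription factor, fell by 1.84 ± 0.36 on the log2 scale, and CD44, a cell surface hyaluronan receptor, fell by 0.92 ± 0.12. These 3 lists passed camera with adjusted p = 2.18e-10, 3.73e-13 and 1.09e-04, and each also passed at adjusted p = 0.0243 with an estimated correlation.

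Estrogen-repressed genes moved the other way in the same libraries: 5 of 12 fell and none rose, with the same counts when adjusted over the list alone. The pro-apoptotic gene BMF (−1.53 ± 0.18) and the p53-inducible gene TP53INP1 (−1.28 ± 0.13) were the clearest members. The list passed camera at adjusted p = 6.44e-04, but had adjusted p = 0.192 with an estimated correlation. Of 7 stem-like markers, ALDH1A3 (−1.20 ± 0.29), an aldehyde dehydrogenase, and CD44 fell and 5 did not pass (camera adjusted p = 0.0215, but adjusted p = 0.192 with an estimated correlation). By fry the estrogen-repressed and stem-like lists had adjusted p = 0.00262 and 0.00298. ALDH1A3 lost its call in 1 of the 6 fits with a library left out (edgeR adjusted p = 0.0699). The receptor gene ESR1 (−0.01, edgeR adjusted p = 0.984), the progesterone receptor gene PGR (−0.24, adjusted p = 0.306), the H3K27 methyltransferase gene EZH2 (0.07, adjusted p = 0.780) and the proliferation marker MKI67 (−0.04, adjusted p = 0.869) did not pass.

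Mitochondrially encoded and ribosomal protein genes, whose transcripts are abundant in the cytoplasm, had positive medians. All 13 mitochondrially encoded genes rose (median 0.89; MT-ND1 1.09 ± 0.14), and the 46 cytosolic ribosomal protein genes had a median of 0.66, with 5 that rose, none that fell and 41 that did not pass (36 rose when adjusted over the list alone). The calls of RPL34, RPS12, RPS16 and RPS19 were lost in 3, 5, 3 and 4 of the 6 fits with a library left out (highest edgeR adjusted p = 0.232, 0.424, 0.178 and 0.138). Camera gave adjusted p = 8.84e-12 and 5.15e-09 for these lists, but adjusted p = 0.196 and adjusted p = 0.517 with an estimated correlation. By fry the mitochondrial list had adjusted p = 0.00568 and the ribosomal protein list adjusted p = 0.182. Beside these lists stands a difference in the make-up of the libraries. Mitochondrial genes took 28.3% ± 4.55 of the counts in TFF1high and 20.4% ± 2.02 in TFF1low libraries (mean and SD, n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Most of this share was mitochondrial ribosomal RNA, at 26.2% ± 4.56 and 19.1% ± 2.03, which is not among the 13 genes of the list. Long noncoding RNA genes took 7.89% ± 0.911 and 11.6% ± 0.327 (exact permutation p = 0.1). Nuclear genes of oxidative phosphorylation had a median of 0.44, with NDUFV1 alone of 19 passing, a call lost in 5 of the 6 fits with a library left out (camera adjusted p = 0.0127 for the list, but adjusted p = 0.517 with an estimated correlation). Without TFF1high or TFF1low replicate A their adjusted p was 0.332 and 0.0912. Replication-dependent histone genes had a median of −0.45, with H2BC21 (−0.75 ± 0.13) and H2BC5 falling among 15, of which H2BC5 lost its call in 5 of the 6 such fits (camera adjusted p = 0.0189, but adjusted p = 0.517 with an estimated correlation). Their adjusted p was 0.317 without TFF1high replicate A and 0.0676 without TFF1low replicate B. The stem-like list likewise had adjusted p = 0.150 without TFF1high replicate C. In the full fit the oxidative phosphorylation and histone lists had fry adjusted p = 0.179 and 0.182.

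Among genes picked for size of change and clean separation of the libraries, those that rose most besides TFF1 were the gastric mucin gene MUC6 (2.81 ± 0.46), the scaffold protein gene PDZK1 (2.24 ± 0.33) and the vesicular nucleotide transporter gene SLC17A9 (2.19 ± 0.27). The 10 that fell most included the long noncoding RNA genes PURPL (9.68-fold lower), MIR205HG (9.13-fold lower) and CASC15 (−2.99 ± 0.35). They also included ADGRL2 (−3.05 ± 0.61), TMTC1 (−2.86 ± 0.21), TENM4 (−2.75 ± 0.28) and the RNA-binding protein gene IGF2BP2 (−2.83 ± 0.55). FAM30A, HOXA5, SOCS3-DT, PLIN4, MT-TI and CRABP1 also rose over 2.00 on the log2 scale, but each lost its call in 1, 3, 3, 4, 5 and 5 of the 6 fits with a library left out (highest edgeR adjusted p = 0.0586, 0.154, 0.0866, 0.207, 0.0906 and 0.268).

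By edgeR quasi-likelihood, 1175 of 14776 genes passed at a false discovery rate of 0.05, with 552 higher and 623 lower in TFF1high cells. Scaled by library size only, 326 were higher and 794 lower, with the median of all genes at −0.05. The count was 740, 765 and 1896 without TFF1high replicates A, B and C, and 644, 683 and 553 without TFF1low replicates A, B and C.

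The second nascent experiment, whose populations were named negative and not negative rather than a top fraction and the rest, gave higher levels of estrogen-induced and G1/S genes as well. STC2 rose 2.33-fold (log2 1.22 ± 0.10 SE, n = 3 per group), RET 2.21-fold (1.15 ± 0.11), and XBP1, a transcription factor of the secretory pathway, 2.56-fold (1.36 ± 0.14). AREG, a ligand of the epidermal growth factor receptor, rose 6.53-fold (2.71 ± 0.30). Of 54 estrogen-induced genes 24 rose, 1 fell and 29 did not pass (29 and 1 when adjusted over the list alone; median 0.57). Of 37 G1/S genes 17 rose and none fell (27 when adjusted over the list alone; median 0.62), led by the replication licensing factor CDC6 (1.35 ± 0.18). Of 10 basal and mesenchymal markers 5 fell and 1 rose (6 and 1 when adjusted over the list alone; median −0.83). TP63 fell by 2.21 ± 0.45 and EGFR by 1.24 ± 0.24 on the log2 scale, whereas CAV1, the coat protein of caveolae, rose (1.41 ± 0.23). By camera these lists had adjusted p = 8.14e-14, 2.48e-15 and 2.58e-04, and adjusted p = 0.0142, 0.0142 and 0.0262 with an estimated correlation.

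Of 12 estrogen-repressed genes 4 fell and none rose (5 fell when adjusted over the list alone; camera adjusted p = 3.45e-05, but adjusted p = 0.117 with an estimated correlation), with BMF at −1.84 ± 0.20 and KLHL24 at −0.94 ± 0.15. Genes of the unfolded protein response split 5 higher, 1 lower and 14 not passing (8 and 1 when adjusted over the list alone). Those that rose included the endoplasmic reticulum chaperone gene HSP90B1 (0.94 ± 0.17) and the disulfide isomerase genes PDIA6 (0.86 ± 0.15) and PDIA4 (0.83 ± 0.14). That list's camera adjusted p was 0.0377, against adjusted p = 0.463 with an estimated correlation. Of 20 p53 targets and apoptosis genes 3 fell, among them SESN2 (−1.36 ± 0.25) and BTG2 (−0.91 ± 0.20; edgeR adjusted p = 0.0824 without TFF1low replicate B), and none rose (8 fell and 1 rose when adjusted over the list alone). Camera gave adjusted p = 0.0349 for them, but adjusted p = 0.396 with an estimated correlation. No single gene of the 42 in the G2/M list passed in experiment 2 by edgeR at the all-gene threshold, although its median of 0.14 had a camera adjusted p of 0.0349, which became adjusted p = 0.452 with an estimated correlation. Stem-like markers had 2 that fell, ALDH1A3 (−1.71 ± 0.36) and CD44 (−0.73 ± 0.12), of 7, while 4 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0327, but adjusted p = 0.184 with an estimated correlation).

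Of 13 mitochondrially encoded genes 8 rose and none fell (12 when adjusted over the list alone; median 0.57). Of 46 ribosomal protein genes RPL3 alone passed (0.68 ± 0.20; median of the list 0.53), with 0 passing when adjusted over the list alone. It lost its call in 5 of the 6 fits with a library left out (highest edgeR adjusted p = 0.182). The camera test returned adjusted p = 3.76e-07 and 3.46e-07 for these lists, but adjusted p = 0.362 and adjusted p = 0.487 with an estimated correlation. None of 19 oxidative phosphorylation genes passed by edgeR (median 0.28; camera adjusted p = 0.0255, but adjusted p = 0.463 with an estimated correlation). The mitochondrial share of counts was again higher in TFF1high libraries, 26.9% ± 3.55 against 18.5% ± 3.03, and the long noncoding share lower, 8.81% ± 0.611 against 13.0% ± 0.834 (n = 3, exact two-sided permutation p = 0.1 each). Mitochondrial ribosomal RNA made up most of the former, 24.5% ± 3.65 against 16.7% ± 2.70. Histone genes did not pass as a list (median 0.05, camera adjusted p = 0.857), and their median was −0.04 when libraries were scaled by size only. ESR1 (0.04, edgeR adjusted p = 0.906), PGR (0.17, adjusted p = 0.542), EZH2 (0.04, adjusted p = 0.901) and MKI67 (0.27, adjusted p = 0.157) did not pass.

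SLC17A9 (2.73 ± 0.31) and MUC6 (2.75 ± 0.51) were again among the genes that rose most, together with the adenosine receptor gene ADORA1 (3.00 ± 0.63), the matrix protein gene MGP (2.47 ± 0.44) and the bone morphogenetic protein regulator BMPER (2.45 ± 0.37). PGM5, a phosphoglucomutase-like protein of adherens junctions, was 13.5-fold lower (−3.76 ± 0.47), GABRP, a GABA receptor subunit, 9.32-fold lower, and the corepressor gene TLE4 fell by 3.13 ± 0.44 on the log2 scale. KLHDC7B and MARK1 also passed as lower, but had 3 counts each over the TFF1high group against 69 and 50 in the TFF1low group, so no fold is given. The imprinted noncoding RNA gene H19 (3.18 ± 0.75), HOXA5, PTGES, CRISP3 and GPNMB passed but lost their calls in 2, 5, 1, 2 and 4 of the 6 fits with a library left out (highest edgeR adjusted p = 0.113, 0.246, 0.0562, 0.102 and 0.108), as KLHDC7B and MARK1 did in 4 each (0.120 and 0.119).

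By edgeR quasi-likelihood, 981 of 14776 genes passed in experiment 2, 469 higher and 512 lower, against 314 higher and 652 lower when scaled by library size only (median of all genes −0.07). The count was 627, 639, 637 and 586 without TFF1high replicate A, TFF1high replicate B, TFF1low replicate A and TFF1low replicate B. List calls were lost without a library as well. G2/M lost its call without TFF1high replicate A (camera adjusted p = 0.148) and without TFF1low replicate B (0.0942). The oxidative phosphorylation list lost it without TFF1high replicate B (0.0814) and TFF1low replicate C (0.0644). The unfolded protein response list lost it without TFF1high replicates B and C and TFF1low replicate C (0.0683, 0.0633 and 0.113). The p53 list lost it without TFF1low replicates A and B and TFF1high replicate C (0.0561, 0.159 and 0.0639), and the stem-like list without TFF1low replicate B and TFF1high replicate C (0.0504 and 0.0957).

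The 2 nascent experiments shared much of their response. Among genes tested in both, 264 were called higher in both and 353 lower in both, where 17.5 and 21.6 would be shared if the calls were independent, and 0 were called in opposite directions at the edgeR threshold. Of the genes called in experiment 1, 97.6% had the same sign in experiment 2. Across genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.645 and Spearman rho = 0.597. A direct test of the difference between the experiments, whose populations were divided differently by the names of their tables, called 0 genes by edgeR quasi-likelihood, by DESeq2 and by limma-voom, with 451 at an unadjusted p under 0.05 by edgeR. The smallest p-values belonged to ANKRD49P1, RAP2A, RNF103, SLC26A2 and UBE2FP1, all with edgeR adjusted p = 1.00, and RAP2A, a small GTPase gene, had a difference of −1.31 ± 0.31. The difference in TFF1 was −0.75 ± 0.37 (adjusted p = 1.00). None of the 26 lists differed between experiments (lowest camera adjusted p = 0.0553). In simulated counts this test recovered 19.4% of genes whose effects differed 2-fold and 72.7% of those that differed 3-fold, so a 2-fold difference would often not have been detectable. The number called the same way in both was 617 and fell to 407 without nascent experiment 1 TFF1low replicate C.

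**Figure D2:**
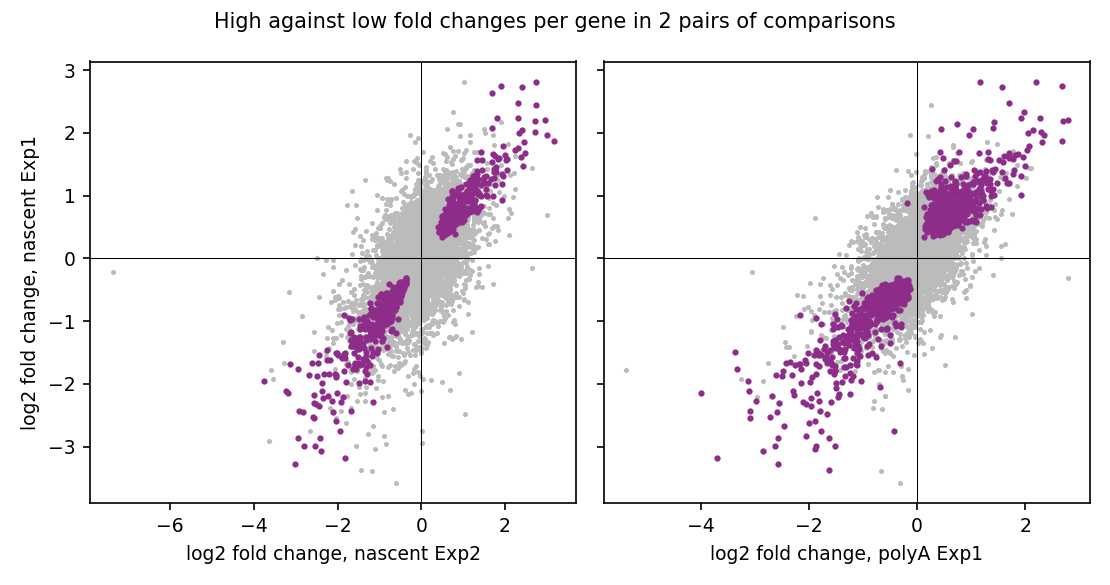
Log2 fold change of TFF1high over TFF1low for each gene, in nascent RNA of experiment 1 (vertical axis) against nascent RNA of experiment 2 (left) and polyA RNA of experiment 1 (right), with genes called in both comparisons in purple and the others in grey. Pearson r across genes was 0.645 on the left and 0.707 on the right.

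In polyA RNA single genes changed with smaller errors. GREB1 rose 1.97-fold (log2 0.98 ± 0.04 SE, n = 3 per group), RET 2.45-fold (1.29 ± 0.05), AREG 4.86-fold (129 ± 9.75 against 26.4 ± 2.21 CPM) and H19 6.40-fold (93.2 ± 6.21 against 14.3 ± 1.28). The plasminogen activator inhibitor gene SERPINE1 was 10.3-fold lower, the membrane glycoprotein gene GPNMB 15.9-fold lower, and ABCA1 fell by 2.85 ± 0.14 on the log2 scale. Of 37 G1/S genes 36 rose, none fell and 1 did not pass (36 rose when adjusted over the list alone; median 0.60), with the uracil glycosylase gene UNG at 0.93 ± 0.05 and the cell division gene CDCA7 at 1.35 ± 0.08. Of 55 estrogen-induced genes 36 rose, 11 fell and 8 did not pass (the same counts when adjusted over the list alone; median 0.49). Of 12 estrogen-repressed genes 10 fell and none rose, with the same counts when adjusted over the list alone, BMF at −1.82 ± 0.07 and the growth regulator gene YPEL3 at −0.97 ± 0.07. Camera gave adjusted p = 2.16e-15, 2.61e-06 and 1.50e-04 for these lists, but adjusted p = 0.195, adjusted p = 0.0972 and adjusted p = 0.195 with an estimated correlation.

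Basal and mesenchymal markers fell in 12 of 16 cases and rose in 1 (13 and 1 when adjusted over the list alone; median −0.80), with LAMC2, a laminin chain of epithelial basement membrane, at −1.14 ± 0.08 and TP63 at −1.53 ± 0.13. CAV1 was again the exception (0.67 ± 0.05). Of 8 stem-like markers 5 fell and 1 rose (6 and 1 when adjusted over the list alone), among them the pluripotency factor gene SOX2 (−1.09 ± 0.08) and ALDH1A3 (−1.23 ± 0.14). By camera the lists had adjusted p = 5.89e-04 and 0.0160, but adjusted p = 0.429 and adjusted p = 0.195 with an estimated correlation. Immediate early genes fell in 14 of 21 cases and rose in 3 (16 and 3 when adjusted over the list alone), with the stress-response factor ATF3 at −1.84 ± 0.15 and JUN at −0.57 ± 0.05. Interferon-response genes fell in 15 of 28 cases and rose in 3 (the same when adjusted over the list alone), with the RNA sensor gene IFIH1 at −0.88 ± 0.09 and IFI6 at −0.90 ± 0.10. These lists had camera adjusted p = 7.18e-04 and 0.0160, but adjusted p = 0.429 and adjusted p = 0.195 with an estimated correlation.

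The series asks about H3K27me3, but these libraries measured RNA only, so polycomb genes bear on it indirectly at most. Whether the listed targets carry the mark in these cells is not known here. Members of the target list of 38 with too few counts, as silenced genes would have, were not tested. Of 26 developmental genes that are textbook polycomb targets, 15 fell, 1 rose and 10 did not pass (the same counts when adjusted over the list alone; median −0.40). HOXD8 fell by 3.04 ± 0.29, HOXC11 by 1.25 ± 0.12 and HOXC13 by 1.00 ± 0.06 on the log2 scale, while FOXC1 rose (0.81 ± 0.06). Of 19 genes of Polycomb repressive complex 1, 12 fell and none rose (the same when adjusted over the list alone), with RYBP at −0.49 ± 0.05 and PCGF3 at −0.45 ± 0.05. These lists passed camera at adjusted p = 5.89e-04 and 8.01e-04, but had adjusted p = 0.181 and adjusted p = 0.195 with an estimated correlation. The list of Polycomb repressive complex 2 and H3K27 demethylase genes split 6 higher and 4 lower of 14 (6 and 5 when adjusted over the list alone) and did not pass (median 0.07 but mean −0.05, camera adjusted p = 0.983). The demethylase genes KDM6B (−0.65 ± 0.07) and KDM6A (−0.38 ± 0.05) fell, and EZH2 rose 1.17-fold (0.22 ± 0.05). In nascent RNA the polycomb target list did not pass in either experiment (12 genes measured, 2 higher in experiment 1, 1 higher and 1 lower in experiment 2; median −0.30 but mean 0.00 in experiment 1; camera adjusted p = 0.533 and 0.189), nor did complex 1 (0.390 and 0.0871) or complex 2 with the demethylases (0.605 and 0.486). Interferon-response genes (0.416 and 0.348) and immediate early genes (0.278 and 0.189) did not pass in nascent RNA either. The polycomb targets called in experiment 1, HOXA5 and FOXC1, each lost their call in 3 of the 6 fits with a library left out. Those called in experiment 2, HOXA5 and PAX9, lost theirs in 5 and 4.

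All 13 mitochondrially encoded genes rose in polyA RNA (median 0.41), as did 12 of 21 oxidative phosphorylation genes with none falling (median 0.19; ATP5F1A 0.49 ± 0.04), both with the same counts when adjusted over the list alone. Camera gave adjusted p = 1.68e-04 and 2.15e-04, but adjusted p = 0.390 and adjusted p = 0.429 with an estimated correlation. The mitochondrial share of counts was 7.27% ± 0.373 in TFF1high and 5.48% ± 0.354 in TFF1low libraries, and the long noncoding share 1.46% ± 0.0551 and 1.69% ± 0.0774 (n = 3, exact two-sided permutation p = 0.1 each). Mitochondrial ribosomal RNA took 2.58% ± 0.203 and 1.78% ± 0.157 of the counts. Ribosomal protein genes had a median of 0.08 and split 20 higher, 6 lower and 20 not passing (20 and 6 when adjusted over the list alone; camera adjusted p = 0.0808). Histone genes fell in 9 of 14 cases and none rose (10 fell when adjusted over the list alone; H2BC21 −0.77 ± 0.05), with camera adjusted p = 3.05e-04 but adjusted p = 0.277 with an estimated correlation. Most histone mRNAs lack a polyA tail, and histone paralogs are nearly identical, so these values are uncertain. G2/M genes did not pass as a list (14 rose, 3 fell and 25 did not pass, with 14 and 3 when adjusted over the list alone; median 0.05, camera adjusted p = 0.135), while MKI67 rose 1.13-fold (0.18). G2/M genes in nascent RNA of experiment 1 had a median of 0.03, or −0.04 under scaling by library size only (camera adjusted p = 0.416), and 0 of 42 passed by edgeR. Of 20 p53 targets 10 fell and 4 rose without passing as a list (10 and 4 when adjusted over the list alone; camera adjusted p = 0.0534), with the cell cycle inhibitor gene CDKN1A at −1.03 ± 0.06 and the stress cytokine gene GDF15 at −1.53 ± 0.10. The same list had camera adjusted p = 0.0843 in nascent RNA of experiment 1.

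**Figure D3:**
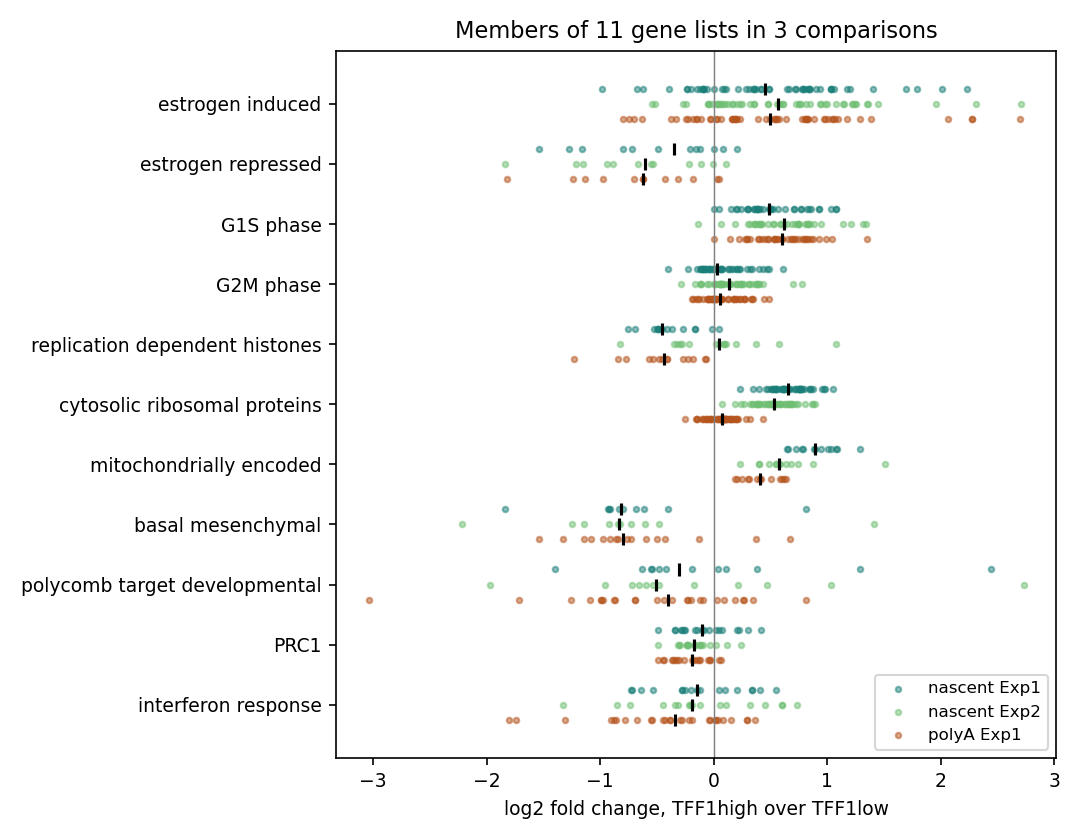
Log2 fold change of TFF1high over TFF1low for the members of 11 fixed gene lists in each of the 3 comparisons, with a point per gene and a black tick at each list's median. G1/S genes had medians of 0.48, 0.62 and 0.60 and basal and mesenchymal markers medians of −0.82, −0.83 and −0.80 in nascent experiment 1, nascent experiment 2 and polyA RNA.

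The genes that rose most in polyA RNA were the calcium-binding protein gene CALB2 (3.02 ± 0.20, or 8.09-fold), SLC17A9 (2.70 ± 0.12), MSMB (2.70 ± 0.19), ADORA1 (2.34 ± 0.15), BMPER (2.31 ± 0.19), PDZK1 (2.27 ± 0.14) and MUC6 (2.20 ± 0.24). Those that fell most included KLHDC7B (41.6-fold lower), CRISP3 (−3.32 ± 0.12), the testis-associated chaperone gene CLGN (−3.28 ± 0.25), PGM5 (−3.13 ± 0.12), GABRP (−3.11 ± 0.12) and the thrombomodulin gene THBD (−2.98 ± 0.09). ESR1 (−0.09, edgeR adjusted p = 0.0698) and PGR (−0.11, adjusted p = 0.108) did not pass. By edgeR quasi-likelihood, 8090 of 17691 genes passed, 4197 higher and 3893 lower, of which 399 and 765 differed at least 2-fold. The polyA libraries were deeper and less variable than the nascent ones (common biological coefficient of variation 4.98% against 16.9%), and 53.9% of genes had non-overlapping groups, where chance gives 10%.

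Most genes called in nascent RNA of experiment 1 were called in the same direction in polyA RNA. Of the genes called in nascent RNA, 470 were higher and 548 lower in both, and 1 was called in opposite directions. If the calls were independent, 146 and 143 would be shared. For nascent experiment 2 and polyA RNA the shared counts were 431 and 469, again with 1 in opposite directions, and Pearson r across genes was 0.748. A test of the difference between the nascent and the polyA effect called 1 of 19904 genes by edgeR quasi-likelihood, against 60 by DESeq2 and 1 by limma-voom, with 1960 at an unadjusted p under 0.05. In simulated counts this test recovered 52.2% of genes whose effects differed 2-fold and 51.5% of those that differed 3-fold, so many differences of that size would not have been detectable. That gene was DMRTA1, a DM-domain transcription factor gene, with a difference of −1.38 ± 0.16 (adjusted p = 0.00122). The difference in TFF1 was −0.61 ± 0.32 and did not pass (edgeR adjusted p = 0.554). Ribosomal protein genes had a median difference of 0.58 and mitochondrially encoded genes 0.43, with no single gene of either list passing by edgeR (1 in each when adjusted over the list alone; camera adjusted p = 2.38e-08 and 1.44e-06, but adjusted p = 0.997 for both with an estimated correlation). The count of 1 became 816 without nascent experiment 1 TFF1high replicate C and 5 without TFF1high replicate B. The 1018 genes called the same way in both fractions became 592, 526 and 622 without the nascent experiment 1 libraries TFF1low A, TFF1low C and TFF1low B.

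The RNA fractions themselves differed widely. NEAT1, a scaffold of nuclear paraspeckles, was 5.76 ± 0.12 higher on the log2 scale in nascent than in polyA libraries of experiment 1 (n = 6 per fraction), MALAT1 5.21 ± 0.10 higher and the imprinted noncoding RNA KCNQ1OT1 5.14 ± 0.10 higher. Of 11 chromatin-retained noncoding RNAs 9 were higher, 1 lower and 1 did not pass, with a median 10.2-fold above polyA (camera adjusted p = 0.00485, but adjusted p = 0.233 with an estimated correlation). All 46 ribosomal protein genes were lower in nascent RNA, by a median of 9.90-fold, among them RPL12 (−3.80 ± 0.24), and so were all 21 oxidative phosphorylation genes (median −2.34). The camera test returned adjusted p = 1.01e-15 and 3.23e-08, but adjusted p = 0.273 and adjusted p = 0.233 with an estimated correlation. Replication-dependent histone genes, most of whose mRNAs lack polyA tails, split 10 higher, 4 lower and 1 not passing and did not pass as a list (camera adjusted p = 0.0935, and adjusted p = 0.501 with an estimated correlation). Among them the linker histone genes H1-5 (6.86 ± 0.27) and H1-4 (6.22 ± 0.19) were higher in nascent RNA. Of 13 mitochondrially encoded genes 12 were lower. In all, 16522 of 19904 genes passed by edgeR quasi-likelihood, 9348 higher and 7174 lower, with the median of all genes at 0.24. These are relative levels within each library.

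Genes grouped by chromosome were tested as sets, and 6, 3 and 4 chromosomes, the mitochondrial one included in each, passed camera in nascent experiment 1, nascent experiment 2 and polyA RNA. Genes of chromosome 14 were higher in TFF1high cells in all 3 comparisons, with medians of 0.19 in nascent experiment 1 (38 of 518 genes rose and 8 fell), 0.18 in nascent experiment 2 (37 rose and 8 fell) and 0.22 in polyA RNA (289 of 605 rose and 53 fell). Camera over chromosomes gave adjusted p = 2.30e-04, 7.05e-05 and 1.96e-06, and adjusted p = 0.0389, 0.0272 and 0.134 with an estimated correlation. Without the filter on low counts the median in nascent experiment 1 was 0.00 (camera adjusted p = 0.225). It was 0.04 in nascent experiment 2 (camera adjusted p = 0.0452) and 0.12 in polyA RNA (0.00276). Scaled by library size only, the medians were 0.11, 0.10 and 0.17, and each passed camera (highest adjusted p = 4.64e-04). Genes of chromosome 3 were lower in all 3 comparisons (medians −0.09, −0.12 and −0.10, camera adjusted p = 0.0157, 0.0384 and 0.0176, but adjusted p = 0.269, adjusted p = 0.336 and adjusted p = 0.0603 with an estimated correlation). Nascent experiment 1 also called chromosomes 19 and 22 higher (medians 0.15 and 0.16) and chromosome 5 lower (−0.09), with camera adjusted p = 0.00920, 0.00466 and 0.0176, but adjusted p = 0.553, adjusted p = 0.252 and adjusted p = 0.260 with an estimated correlation. Mitochondrial genes had medians of 0.92, 0.64 and 0.51 in the 3 comparisons (camera adjusted p = 1.73e-13, 1.35e-08 and 8.52e-05, but adjusted p = 0.169, adjusted p = 0.259 and adjusted p = 0.196 with an estimated correlation). The count of 6 became 3 without nascent experiment 1 TFF1high replicate B, and that of 3 became 5 without nascent experiment 2 TFF1low replicate B or TFF1high replicate C. Chromosome 21, which carries TFF1, passed as lower in polyA RNA (median −0.15, camera adjusted p = 0.00181, but adjusted p = 0.148 with an estimated correlation).

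**Figure D4:**
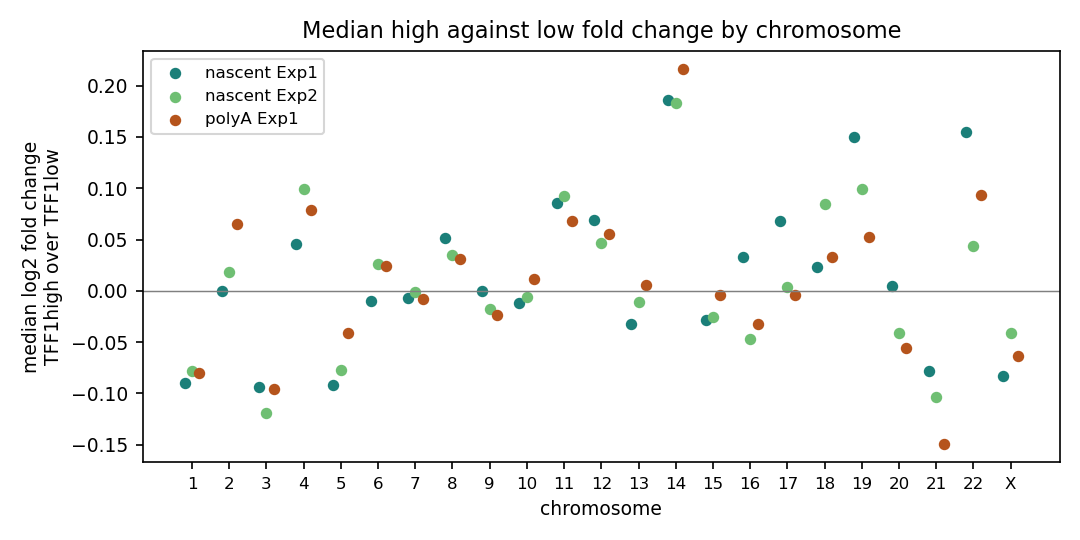
Median log2 fold change of TFF1high over TFF1low for the genes of chromosomes 1 to 22 and X in the 3 comparisons. Chromosome 14 had medians of 0.19, 0.18 and 0.22 in nascent experiment 1, nascent experiment 2 and polyA RNA.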

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

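No test in this part was chosen after its result was seen. DMRTA1, on chromosome 9, was marked because the TFF1high against TFF1low effect differed between RNA fractions of experiment 1 in a direct edgeR quasi-likelihood test (difference −1.38 ± 0.16 on the log2 scale, adjusted p = 0.00122 over 19904 genes). In nascent RNA it was lower in TFF1high cells, at −1.68 ± 0.20 (22.7 ± 1.25 against 73.4 ± 9.19 CPM, mean and SD, n = 3), and in nascent RNA of experiment 2 it was at −1.51. In polyA RNA the change was −0.31 ± 0.09 (10.0 ± 0.637 against 12.4 ± 0.565 CPM). Under 19 alternatives the difference ran from −1.47 to −1.28 and the adjusted p from 5.98e-10 to 0.0136. Of 100 drawn splits of the 12 libraries, 3 called at least 1 gene, the real one included. The splits exchanged nascent and polyA libraries within each population, so most drawn groups held both fractions. The spread between fractions then leaves few calls in any case, so the share of splits does not bear on DMRTA1. The highest other count, 6933, reflects the same structure of the samples.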

How the results depend on the processing

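Thinning and leaving out mitochondrial and ribosomal protein genes were chosen after the data were seen. No named gene and no fixed list reversed its direction with a call under any alternative. Of the alternatives for named genes 7735 kept direction and side of the threshold, 145 gained and 328 lost a call. For lists these counts were 1121, 26 and 28. Counts of genes, lists or chromosomes stayed within 1.5 times in 222 cases and moved further in 42.

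At a false discovery rate of 0.10 nascent experiments 1 and 2 called 1909 and 1566 genes. A minimum fold of 1.2 left 538, 521 and, in polyA RNA, 3481 genes, as its construction implies. limma-voom called 2816 in nascent experiment 1, where the cause was not tested. With the replicate letter as a block (replicate block) the counts were 1641, 1481 and 8723, of which 1127, 970 and 7993 were shared with the fit without it. Deviations of same-letter TFF1high and TFF1low libraries correlated from −0.0694 to 0.0599 in nascent experiment 1, 0.0744 to 0.386 in experiment 2 and 0.0146 to 0.0539 in polyA RNA. Every polyA library correlated best with its own letter, and so, more strongly, did letters B and C of nascent experiment 2 (0.247 and 0.386), hints of pairing. TFF1high A of experiment 2 correlated better with TFF1low B (0.144) than with TFF1low A (0.0744). No comparison had all 3 pairs over 0.1 and the labels name no shared culture, so pairing stays open. PolyA RNA gave 3466 genes with all 12 libraries of experiment 1 in the fit. That fit shares 1 spread per gene between the fractions. Its common biological coefficient of variation was 11.7%, against 4.98% for polyA RNA alone (cause not tested further). Thinned to the smallest library of the fit, the counts were 727, 840 and 7128, and polyA RNA thinned to the smallest nascent library gave 3105, so thinner libraries gave fewer calls. Scaling by library size only changed the split to 326 higher and 794 lower in experiment 1 and 314 and 652 in experiment 2. The difference between fractions called 243 genes without a filter on low counts and 60 with DESeq2 (cause not tested). With an estimated correlation 3, 3 and 0 lists and 1, 1 and 0 chromosomes passed in nascent experiment 1, experiment 2 and polyA RNA. Fry called 6, 11 and 19 lists in these comparisons. Camera adjusted p rose even without correlation between genes. In nascent experiment 1 the basal and mesenchymal list had an estimated correlation of −0.00915, under the preset 0.01. Its camera adjusted p still rose from 1.09e-04 to 0.0243. Without a filter 1 chromosome passed in nascent experiment 1 and 2 in polyA, where 2 also passed with all 12 libraries. Without TFF1 and mitochondrial genes 1 passed in experiment 2, where the mitochondrial set is then empty and the further loss has no tested cause.

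Leaving out 1 library gave 553 to 1896 genes in nascent experiment 1, 586 to 994 in experiment 2, 6819 to 7893 in polyA RNA, 1 to 816 for the difference between fractions and 16626 to 17187 for nascent against polyA level. It gave 8 to 10, 9 to 12 and 12 to 14 lists, and 3 to 6, 2 to 5 and 4 chromosomes. Genes called in the same direction ran from 407 to 690 between nascent experiments and from 526 to 1414 between nascent and polyA RNA. The values 1896, 816, 690 and 1414 came without nascent experiment 1 TFF1high replicate C, and 553, 407 and 526 without TFF1low replicate C. The 3 chromosomes of experiment 1 came without TFF1high replicate B, and the 5 of experiment 2 without TFF1low replicate B or TFF1high replicate C. Calls held in every such fit for 43 of 76 named calls in nascent experiment 1, 48 of 72 in experiment 2 and 122 of 123 in polyA RNA. The cause of these shifts was not tested.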

Other observations

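The tests of a whole-cell rise in ribosomal protein and mitochondrial transcripts, of copy number, of S-phase share and of shifts that allow for the choice of chromosome were chosen after the results were seen. Genes of the secretory pathway and of hormone signalling moved in both directions in polyA RNA, where calls were most numerous, and none of the following lists passed camera there. Of 14 secretory and mucin genes 7 rose and 6 fell, the same when adjusted over the list alone (median 0.00, camera adjusted p = 0.919). Of 22 unfolded protein response genes 9 rose, among them XBP1 (0.80 ± 0.04) and PDIA4 (0.60 ± 0.04), and 8 fell, with the stress factor DDIT3 at −1.21 ± 0.09 (9 and 9 when adjusted over the list alone; median −0.03 although the test pointed up, camera adjusted p = 0.919). Luminal epithelial genes rose in 8 and fell in 3 of 16 cases (9 and 4 when adjusted over the list alone; camera adjusted p = 0.173). The 20 estrogen receptor cofactor genes, ESR1 included, split 3 higher and 9 lower (3 and 11 when adjusted over the list alone; camera adjusted p = 0.0976). Endocrine resistance and growth factor genes split 5 higher and 9 lower of 20 (5 and 9 when adjusted over the list alone; camera adjusted p = 0.201), with EGFR at −0.84 ± 0.09.

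Of 20 cholesterol synthesis genes 12 rose and 4 fell (12 and 5 when adjusted over the list alone; camera adjusted p = 0.0808). Heat shock genes rose in 8 and fell in 5 of 14 cases (8 and 5 when adjusted over the list alone; camera adjusted p = 0.273), and hypoxia and glycolysis genes rose in 9 and fell in 10 of 24 (9 and 12 when adjusted over the list alone; camera adjusted p = 0.540). Around TFF1 on chromosome 21, 3 of 13 neighbours rose, among them the protease gene TMPRSS3 (1.24) and the trefoil peptide gene TFF3 (0.48), and 3 fell (4 and 6 when adjusted over the list alone; median −0.15 but mean 0.04, camera adjusted p = 0.757). Chromatin-retained noncoding RNAs split 1 higher and 3 lower of 9 (1 and 3 when adjusted over the list alone; camera adjusted p = 0.533). In nascent experiment 1 that list had a median of 0.06 but a mean of −0.16, with NEAT1 at −1.22 and MALAT1 at −0.55 lower and PVT1 at 0.58 higher. Of 13 immune marker genes 3 were measured and none passed by edgeR, nor when adjusted over the list alone (camera adjusted p = 0.919).

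Ribosomal protein and mitochondrially encoded lists had positive medians in TFF1high nascent libraries, calls that were lost with an estimated correlation (adjusted p = 0.517 and 0.487 for ribosomal protein genes, 0.196 and 0.362 for mitochondrial genes, in experiments 1 and 2). To test for the same rise in whole-cell RNA, the polyA median of each list was set against its nascent one in experiment 1. It was 11.7% of it for ribosomal protein genes and 46.3% for mitochondrial genes. These ratios carry no spread, and by camera with an estimated correlation neither list passed as a difference between fractions. The same rise in whole-cell RNA therefore stays open for both lists. More cytoplasmic RNA in the chromatin fraction of TFF1high cells may contribute: across other genes the nascent effect of experiment 2 fell with the nascent over polyA level (Spearman rho = −0.221). The polyA effect itself had rho = −0.150 with that level, and the nascent effect minus the polyA effect had rho = −0.123 over 13641 genes, so part of the relation was shared with polyA RNA and part was not. A change in the RNA content of the populations themselves stays open and untested.

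Chromosome 14 genes were higher in all 3 comparisons by camera (adjusted p = 0.0389, 0.0272 and 0.134 with an estimated correlation), and 71.9% of them lay above the median of all genes in polyA RNA, so the rise was not that of a few genes, although this share largely restates the raised median. A correction for GC content, gene length and expression level kept 98.9% of the polyA median, which argues against these as the whole cause. Chance placement of co-regulated neighbours stays open: 0.838% of circular shifts of the gene order gave a median as high, but chromosome 14 was singled out of 23, and in 18.3% of shifts some chromosome had a standardised median as large. All 8 segments of 10 Mb that could be measured lay above the median of all genes in every comparison. This largely restates the raised median for which the chromosome was chosen. Outside chromosome 14 the medians of 238 such segments also correlated between comparisons (Pearson r from 0.767 to 0.836). The segments therefore cannot decide on a copy-number difference between subclones of the culture, which stays open. No DNA was measured in these libraries, and regulation along the chromosome stays open as well.

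G1/S genes were higher in all 3 comparisons by camera (adjusted p = 0.0243, 0.0142 and 0.195 with an estimated correlation). A larger share of cells in S phase would raise replication-dependent histone genes alike. The lowest of 3 lower bounds (95%) of the difference, G1/S minus histone median, was 0.373. These bounds come from a bootstrap over the genes of each list, which are not independent, and hold no spread between libraries. PolyA libraries measure histone mRNA poorly, and histone counts are uncertain in nascent RNA too. In nascent experiment 1 the histone list lost its call without TFF1high replicate A (camera adjusted p = 0.317). In nascent experiment 2 its median was 0.05, or −0.04 when scaled by library size only. The test therefore cannot decide on the S-phase share, which stays open. More cytoplasmic RNA in the chromatin fraction was argued against as the whole cause, since it needs a clearly larger nascent than polyA effect, while the list's medians were 0.48 and 0.62 in nascent experiments 1 and 2 and 0.60 in polyA RNA (median difference in experiment 1 −24.2% of the nascent median, which did not pass as a difference, camera adjusted p = 0.387, and adjusted p = 0.997 with an estimated correlation). A response of these genes to estradiol that differs between the populations is a possible biological explanation. The labels give estradiol for both populations and do not explain the difference. It stays untested because no library without estradiol is among these samples.

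For TFF1high against TFF1low, 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real split called 1175, 981 and 8090 genes in nascent experiment 1, nascent experiment 2 and polyA RNA, and in each the highest other split called 0 genes by edgeR, so 1 of 10 was as large. Every other split put TFF1high and TFF1low libraries in both groups. The real difference then entered the spread and left few calls in any case, so the contrast with 0 carries little weight. For the difference between nascent experiments, which called 0 genes by edgeR (451 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom), all 100 drawn splits were as large. No count can be under 0, so this outcome was fixed in advance and says nothing about a difference. For nascent against polyA level 1 of 100 drawn splits, the real one, reached 16522 genes, and the highest other reached 7971. That share is under 0.05, but the splits treat libraries as independent. Most drawn groups also held both fractions, which lowers their counts in any case. The labels do not say that replicates came from separate cultures.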
